A study of Danio rerio with 12 samples.

How the data were processed

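RNA was measured by sequencing of poly(A)-selected libraries, made with a directional kit, from the 2 eyes of each of 12 zebrafish. Genotype, age and replicate number of each sample were taken from its title. There were 3 libraries in each of 4 groups (wild type and gmds heterozygotes, at 1 and at 2 years). The columns of the 1-year table carry a genotype and a number but no age, so their age was taken from the table. Per the labels, RNA had an integrity number of at least 7. No sex, clutch or sequencing date was given.

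The values are estimated counts per transcript, which the authors deposited in 2 tables, 1 for each age. Per the file headers they were made by HOMER's repeat and gene quantification over the exons of RefSeq transcripts of danRer11, without adjustment for depth and with reads of both strands counted. Per the submitters' processing notes, STAR and HOMER were used with GRCz11 (danRer11), and their versions are not given in the sources used here. Because counting took no account of strand, overlapping and antisense genes cannot be separated, and reads of near-identical copies can be split between them. All values were whole multiples of 0.5 (tolerance 1e-06) and 59% were whole, so the deposited estimated counts were rounded to whole numbers (0.5 upward) before any test. Each table had 16286 transcripts, matched between tables by transcript identifier. Of these, 1984 had several genomic copies and 226 were listed at a different position in the 2 tables, all of them with several copies. Where a symbol had several transcripts (700 symbols), the transcript with the highest mean count was kept, a choice made after the tables were seen, which left out 875 transcripts and left 15411 genes. Coordinates are those of the tables, on GRCz11. No mitochondrially encoded gene was among the transcripts (0 of 16286).

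Counts on genes ranged from 13521122 to 34173160 per library. Of HOMER's tags, 50.4% to 62.0% fell on the genes kept (58.7% ± 3.20, SD, n = 3, in wild type and 53.0% ± 2.71 in heterozygotes at 1 year). The floor of a library is the CPM, on the TMM scale, that 3 counts correspond to. Counting intervals (95%, exact) and floors cover counting error only, since reads were not traced to molecules. The common biological coefficient of variation was 26.3%.

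Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr on the 4 groups, which left 12202. Libraries were scaled by TMM, and CPM values use these scaled totals. The main test was edgeR's quasi-likelihood test on a means model of the 4 groups over all 12 libraries (8 residual degrees of freedom, 3.68 prior), with Benjamini-Hochberg adjustment and a threshold of 0.05. There were 5 comparisons, namely heterozygotes against wild type at 1 year, the same at 2 years, the difference between these effects (2 years minus 1 year), and 2 years against 1 year within wild type and within heterozygotes. Standard errors of log2 fold changes are those of the fitted model. DESeq2's Wald test on the same genes was an alternative, with 41 genes left without an adjusted p in each comparison.

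Of 28 gene lists, 27 had at least 5 tested genes and were tested. The lists held 1286 entries, of which 1094 matched a gene, 13 of them by a synonym (the match of col4a1 to col4a5 is doubtful), and 918 genes were tested, 8 of them in several lists. The list of mitochondrially encoded genes matched 0 genes. The others were GDP-fucose synthesis and fucosylation, Notch signalling, glaucoma-associated orthologues, rods, cones, ganglion cells, Mueller glia, bipolar cells, amacrine and horizontal cells, pigment epithelium, lens, corneal and surface epithelium, extracellular matrix, macrophages with microglia and complement, lymphocytes, interferon response and antigen presentation, heat shock and unfolded protein response, immediate early genes, the circadian clock, apoptosis, proliferation, ribosomal proteins, the respiratory chain, skeletal muscle, erythrocytes, myelin, and blood vessels. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists of a comparison. The tests were repeated with the correlation estimated per list and with fry, which tests whether a list's genes move, on balance, one way and does not compare the list with other genes. Members were also adjusted over the list alone.

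The genes named were chosen by a rule. It took gmds, then, among genes past the threshold with a mean of at least 1 CPM, a symbol other than a clone or locus name and no overlap between the groups, the 10 with the largest fold change in each direction (5 for the difference between ages). It added up to 4 members of each list past the threshold, or otherwise up to 2 abundant ones. Where fewer than 5 genes passed, the 5 with the smallest p in each direction were given as values. This rule took 11, 0, 0, 1 and 4 genes past the threshold in the 5 comparisons. Of the list members that passed adjusted over the list alone, some were named in addition and the others given as counts. The groups, comparisons, tests, gene lists, rule and alternatives were fixed before the data were examined, except where stated.

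The replicate numbers come from the labels, which do not say whether a number marks a shared clutch or day. At 1 year, the deviations of same-numbered libraries from their group means correlated at 0.32, 0.17 and 0.12 across genes, all above 0.1, so the numbers were taken to pair the 1-year libraries. The fit with the number as a block left 4 residual degrees of freedom.

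Alternatives were scaling by size factors in the manner of DESeq2 or by total counts, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2, the groups of a comparison alone, the replicate block, an adjusted p of 0.1, a fold threshold of 2, and each library left out in turn. Chosen after seeing the data were a robust quasi-likelihood fit, voom with library quality weights, all transcripts in place of 1 per symbol, removal of each library's trend of log2 CPM on transcript length, the block in the 1-year libraries alone, and leaving out both second libraries at 1 year, which had low quality weights (0.41 and 0.5).

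The edgeR steps were tested on simulated data for heterozygotes against wild type at 1 year, over 12136 genes with real means and library sizes. Of 50 genes changed by each fold, 10% were called at 1.5-fold, 40% at 2-fold, 90% at 4-fold and 100% at 8-fold, and 5 of 125 calls were unchanged genes. The changed genes were drawn among those with a mean of at least 5 CPM, so these shares do not cover genes of lower counts. In the real data gngt2a, with a log2 fold change of -7.26 at 1 year, did not pass edgeR's test (adjusted p = 0.0951). The shares therefore need not hold for genes that vary strongly between fish. For the 2-year comparison, simulated with no change over 12136 genes, 0 genes were called by edgeR. For the list test, over 12150 genes, 1 list of 40 genes lowered by 0.5 (log2) was called and 0 of 20 unchanged lists were. The simulated genes were drawn independently of each other, while the correlation estimated for real lists reached 0.64 (erythrocyte genes at 1 year). So the simulation cannot tell how often correlated lists are called falsely at the preset correlation. Base composition was not checked, because no genome sequence was used here.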

Results

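RNA was sequenced from the eyes of adult zebrafish (Danio rerio) that carried 1 mutant copy of gmds, made by genome editing, and of their wild-type siblings. The gene gmds encodes GDP-mannose 4,6-dehydratase, the enzyme that starts the de novo route to GDP-fucose, 1 of its sources in the cell. GDP-fucose is the donor for all fucosylated glycans. Each of the 12 samples held both eyes of 1 fish, and there were 3 wild-type and 3 heterozygous (gmds +/-) fish at 1 year of age and the same numbers at 2 years. The study asked how the transcriptome of the heterozygous eye differs from that of wild-type siblings at each age, in a project on glaucoma. Counts on genes ranged from 13521122 to 34173160 per library, so that 3 counts corresponded to 0.0868 to 0.229 CPM (counts scaled to library size with edgeR's TMM factors). The gene with the most counts in all 12 libraries was rho, which encodes rod opsin and took 3.4% to 8.57% of them. Each sample was a separate fish, so the p-values of the main test rest on the spread between fish, pooled over the 4 groups. That test took no account of the pairing of the 1-year libraries by number. The labels do not state the sex of the fish. Among libraries of 1 group, log CPM correlated at 0.949 to 0.988. Their counts differed by more than sampling noise (chi-square per degree of freedom 31.4 to 144), so no pair of them looked like copies of 1 library.

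The RNA of gmds itself (chromosome 20, 26709009 to 26822550, minus strand, GRCz11) was lower in all 6 heterozygous libraries than in any wild-type library of the same age. At 1 year the wild-type fish had 33, 34 and 37 CPM (34.7 ± 2.28, SD, n = 3). The heterozygotes had 15, 27 and 15 CPM (19.0 ± 6.97, n = 3), which is 54.7% of wild type. At 2 years the wild-type fish had 30, 26 and 41 CPM (32.3 ± 7.68, n = 3). The heterozygotes had 17, 15 and 16 CPM (16.0 ± 1.25, n = 3), which is 49.7% of wild type. The log2 fold change was -0.87 ± 0.23 (SE) at 1 year and -1.01 ± 0.23 at 2 years, and the difference between the ages was -0.14 ± 0.33 (adjusted p = 0.954). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over all genes, the adjusted p was 0.165 at 1 year and 0.991 at 2 years. Adjusted over the list alone of GDP-fucose genes, gmds fell at both ages. A two-sided exact permutation test of log CPM gave p = 0.1 at each age, the smallest that 3 against 3 fish allow. With labels permuted within each age and both ages averaged, p was 0.005, the smallest that the 400 labellings allow. These labellings took no account of the pairing of the 1-year libraries by number. Labellings that respect the pairs are fewer, so the smallest p they allow is larger. Heterozygous replicate 2 at 1 year, at 27 CPM, was the nearest to wild type, and without it the 1-year log2 fold change was -1.2 (adjusted p = 0.0491).

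**Figure D1:**
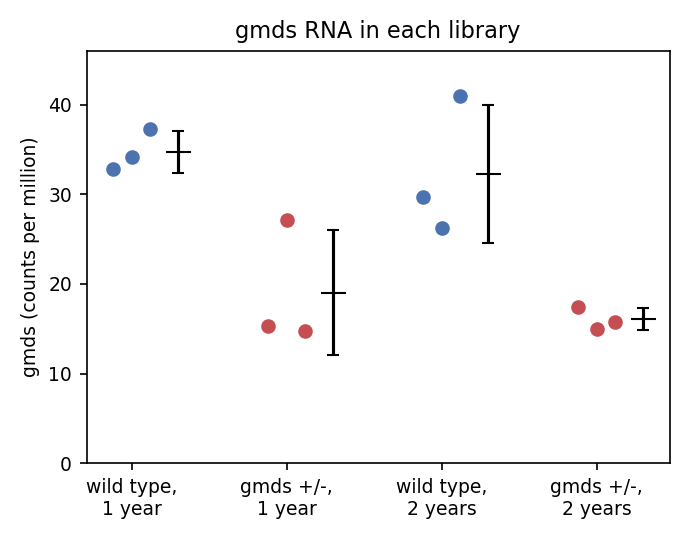
The vertical axis shows gmds RNA in CPM, with 1 point per library (blue, wild type; red, gmds +/-) and, beside each group of 3 libraries, a bar for the mean and whiskers for 1 SD. Heterozygous libraries lie between 15 and 27 CPM and wild-type libraries between 26 and 41 CPM, with no overlap within an age.

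At 1 year, heterozygous eyes had almost no RNA of tk2, the mitochondrial thymidine kinase gene, which fell from 23.6 ± 6.54 to 1.44 ± 0.44 CPM (SD, n = 3 each; log2 fold change -4.06 ± 0.39). Its neighbour on chromosome 7, cmtm3, fell as well, from 5.46 ± 0.083 to 1.24 ± 0.297 CPM. On that chromosome tk2 lies at 44599313 to 44605081 and cmtm3, on the other strand, at 44608347 to 44621278. A microsomal epoxide hydrolase gene, ephx1, fell from 210 ± 1.1 to 117 ± 9.80 CPM. The glucuronosyltransferase gene ugt2b6 fell from 9.76 ± 1.3 to 3.04 ± 0.362 CPM. The genes that rose included mlf1 (17.7 ± 2.85 to 46.8 ± 9.45 CPM), the muscle calcium-release channel gene ryr1b (8.68 ± 1.04 to 19.8 ± 2.98 CPM) and the centriolar satellite gene pcm1 (30.7 ± 6.56 to 67.3 ± 4.03 CPM). Also higher were atf4b, a transcription factor gene of the integrated stress response (57.0 ± 9.58 to 116 ± 4.96 CPM), and syne2a, which encodes a giant nuclear-envelope protein (160 ± 14.7 to 273 ± 12.1 CPM). In all, 14 of 12202 genes tested passed an adjusted p of 0.05, 7 higher and 7 lower, and their libraries did not overlap between genotypes. With library totals as the only scaling, 19 genes passed, 13 higher and 6 lower.

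The adjusted p at 1 year was 0.00358 for tk2 and 0.0152 to 0.0451 for the other 13 genes. The log2 fold changes were -2.12 ± 0.30 for cmtm3, -1.68 ± 0.27 for ugt2b6 and -0.84 ± 0.11 for ephx1. They were 1.40 ± 0.22 for mlf1, 1.18 ± 0.17 for ryr1b, 1.13 ± 0.18 for pcm1, 1.02 ± 0.16 for atf4b and 0.77 ± 0.12 for syne2a. For rfesd, a gene for a Rieske-domain protein on chromosome 21, the 3 wild-type libraries held 437 counts and the 3 heterozygous libraries 1. The ratio was 331 (95% counting interval 59.1 to 13100, counting error only). A further 3 of these genes lay outside the rule for named genes because of low counts or a clone name and were chosen after their values were seen. They were acap1 (0.0584 CPM in wild type and 1.93 CPM in heterozygotes), ugt2b3 (1.23 and 0.181 CPM) and zgc:103586 (0.0111 and 1.00 CPM). The annotated atf4b copy lies on an alternative contig of chromosome 3, and ugt2b6 and ugt2b3 belong to a family of similar genes on chromosome 5, so their counts are uncertain. DESeq2 called 350 genes (198 higher, 152 lower), the 14 among them, and 1752 genes had an unadjusted p under 0.05.

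Of the 14 calls at 1 year, 1 (tk2, adjusted p = 0.0453) was kept when the replicate number, which pairs the 1-year libraries, was added as a block. The fold changes hardly moved with it (ephx1 -0.85, cmtm3 -2.14, pcm1 1.15, mlf1 1.39, syne2a 0.77), and the 13 calls ended at adjusted p = 0.101 to 0.148 with 4 residual degrees of freedom. The count was 1 without any 1 of the 3 wild-type libraries, 5 and 86 without heterozygous replicate 1 or 3, and 5 without both second libraries. It was 9 with each library's trend on transcript length removed, after which ryr1b was 0.61 (adjusted p = 0.2), pcm1 0.84 (0.122) and syne2a, with a transcript of 27206 bases, -0.03 (0.936).

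Of the 27 fixed gene lists with enough measured members, 9 were called at 1 year by camera with a preset correlation of 0.01, and 0 with the correlation estimated per list. The rotation test fry called 3, those of the lens, GDP-fucose and rod genes. Genes of the lens lay lowest: 40 of 42 were below 0 with a median log2 fold change of -1.05 (adjusted p = 3.11e-31 preset, adjusted p = 0.146 with an estimated correlation, fry adjusted p = 0.0427). None of them passed over all genes, and 28 of the 42 fell when adjusted over the list alone. The crystallin genes, which encode the structural proteins of the lens fibre, included cryba2a (2020 CPM in wild type and 909 CPM in heterozygotes, -1.15 ± 0.20) and cryaa (3602 and 1671 CPM, -1.11 ± 0.31). Crystallin paralogs are similar in sequence, so single members are less certain than the list. The mean lens score, the mean centred log2 CPM of the list, was 0.79 ± 0.13 (SD, n = 3) in wild-type fish at 1 year and -0.30 ± 0.28 in heterozygotes. At 2 years it was -0.22 ± 0.53 in wild-type fish and -0.27 ± 0.25 in heterozygotes, so wild-type fish at 1 year stood apart from the other groups.

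The list of interferon response and antigen presentation was lower in heterozygotes at 1 year, with 29 of 35 genes below 0 and a median of -0.49 (adjusted p = 8.54e-07, and adjusted p = 0.485 with an estimated correlation). Adjusted over the list alone 5 of its genes fell, and 0 over all genes. They were the interferon-induced isg15 (-1.65 ± 0.40) and rsad2 (-1.64 ± 0.46), the transcription factor irf3 (-0.99 ± 0.27), and b2m (-0.93 ± 0.20) and mhc1zba (-0.67 ± 0.20), which belong to antigen presentation. Lymphocyte genes had a median of -0.18 (n = 21, adjusted p = 0.029, and adjusted p = 0.489 with an estimated correlation). Adjusted over the list alone 4 fell, against 0 over all genes: the T cell genes cd8a (-2.49 ± 0.76), zap70 (-1.52 ± 0.45) and il7r (-1.32 ± 0.37), and ccl38.6 (-1.78 ± 0.56). Genes of the corneal and surface epithelium (n = 30, median -0.59, adjusted p = 3.69e-04), the pigment epithelium (n = 25, -0.44, 5.08e-05) and Mueller glia (n = 25, -0.23, 0.0441) were also lower, at adjusted p = 0.704, adjusted p = 0.485 and adjusted p = 0.485 with an estimated correlation. Skeletal muscle genes (n = 46, median 0.51, adjusted p = 0.00945), bipolar cell genes (n = 22, 0.24, 0.0233) and retinal ganglion cell genes (n = 34, 0.18, 0.029) were higher, at adjusted p = 0.935, adjusted p = 0.489 and adjusted p = 0.489 with an estimated correlation. Within the muscle list ryr1b rose over all genes and alone. Of the ganglion cell list 0 passed over all genes and 2 rose adjusted over the list alone, the neurofilament gene neflb (0.94 ± 0.16) and rbpms2a (0.69 ± 0.17). The muscle call ended without wild-type replicate 1 (median 0.38) or 3 (0.45) or heterozygous replicate 1 (0.32) or 3 (0.24) at 1 year. The ganglion cell call ended without wild-type 2 (0.06) or heterozygous 1 or 3 (0.13 each), and the bipolar call without wild-type 1 or heterozygous 1 (0.24 each). Lymphocytes were no longer called without wild-type 1 (-0.13), heterozygous 1 (-0.22) or 3 (-0.26), Mueller glia without wild-type 2 (0.06) or heterozygous 3 (-0.16), and cornea without wild-type 2 (-0.21) or heterozygous 1 (-0.23). With the length trend removed the Mueller glia (-0.14, adjusted p = 0.121) and lymphocyte calls (-0.18, 0.052) ended. Without both second libraries the Mueller glia call ended (-0.16, adjusted p = 0.247), and ganglion cell (0.10), corneal (-0.23), lymphocyte (-0.28) and muscle genes (1.05) kept theirs. Muscle genes were at 0.84 without heterozygous 2, and Mueller glia genes at -0.40 and -0.35 without wild-type 1 and 3.

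The other lists were not called by camera at 1 year. The GDP-fucose list had a median of -0.14 with 11 of 15 genes below 0 (adjusted p = 0.251), and fry called it lower (fry adjusted p = 0.0499). This list holds gmds itself, the only member that fell adjusted over the list alone. Since fry was not run without gmds, its call does not show a fall of the other members. Rod genes had a median of 0.11 with 18 of 23 above 0 (adjusted p = 0.117), and fry called them higher (fry adjusted p = 0.0499). The median was 0.00 for Notch signalling, whose receptors carry O-fucose (n = 36, adjusted p = 0.692). The orthologues of glaucoma-associated genes had a median of 0.09 (n = 32, adjusted p = 0.692), and pax6a rose when adjusted over the list alone (0.64 ± 0.15), against 0 over all genes. Cone genes had a median of -0.04 (adjusted p = 0.692), amacrine and horizontal cell genes 0.12 (0.259), macrophage, microglia and complement genes 0.15 (0.692), and extracellular matrix genes -0.06 (0.692). In the cone list opn1lw1 (1.58 ± 0.42) and opn1mw2 (0.97 ± 0.26) rose and gngt2a fell (381 ± 83.3 to 2.44 ± 2.6 CPM), adjusted over the list alone and not over all genes (gngt2a adjusted p = 0.0951). In the macrophage list the complement genes c3b.1 (0.035 to 1.75 CPM) and c3b.2 (no count in wild type and 2.85 ± 1.58 CPM in heterozygotes) rose and cd74b fell (-0.69 ± 0.18) in the same way. The median was -0.04 for heat shock and the unfolded protein response (adjusted p = 0.764), in which atf4b rose. Medians were 0.21 for immediate early genes (adjusted p = 0.566), -0.10 for apoptosis (0.244), -0.08 for cell proliferation (0.472) and -0.03 for the circadian clock (0.957). Ribosomal protein genes had a median of -0.05 (adjusted p = 0.692), respiratory chain genes -0.03 (0.523) and myelin genes -0.09 (0.566). Erythrocyte genes had a median of -0.22 (adjusted p = 0.117, and 0.0093 with the replicate block) and blood vessel genes 0.17 (0.117, and 0.0384 with the block). With the block in the 1-year libraries alone erythrocyte genes were called (camera adjusted p = 0.0151) and blood vessel genes were not (0.053). The mean over members was above 0 for the matrix list (0.03) and the clock list (0.12), opposite in sign to their medians, while the clock list's test pointed up and the matrix list's down. With 1 library left out, 8 of these lists were called. Without heterozygous replicate 2 these were amacrine (0.15), apoptosis (-0.34), ribosomal (-0.24) and blood vessel genes (0.33), and without heterozygous 1 respiratory (-0.32) and erythrocyte genes (-0.63). Without wild-type 2 they were matrix (-0.18), immediate early (0.42), erythrocyte (-0.41) and, turned upward, ribosomal genes (0.15). Blood vessel genes (0.29) were called without wild-type 1 or 3, and ribosomal (-0.14) and respiratory genes (-0.13) without wild-type 3. Without both second libraries macrophage genes were called lower (-0.33, adjusted p = 0.00916), as were apoptosis (-0.28), proliferation (-0.20) and matrix genes (-0.13), and respiratory genes were called higher (0.21).

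**Figure D2:**
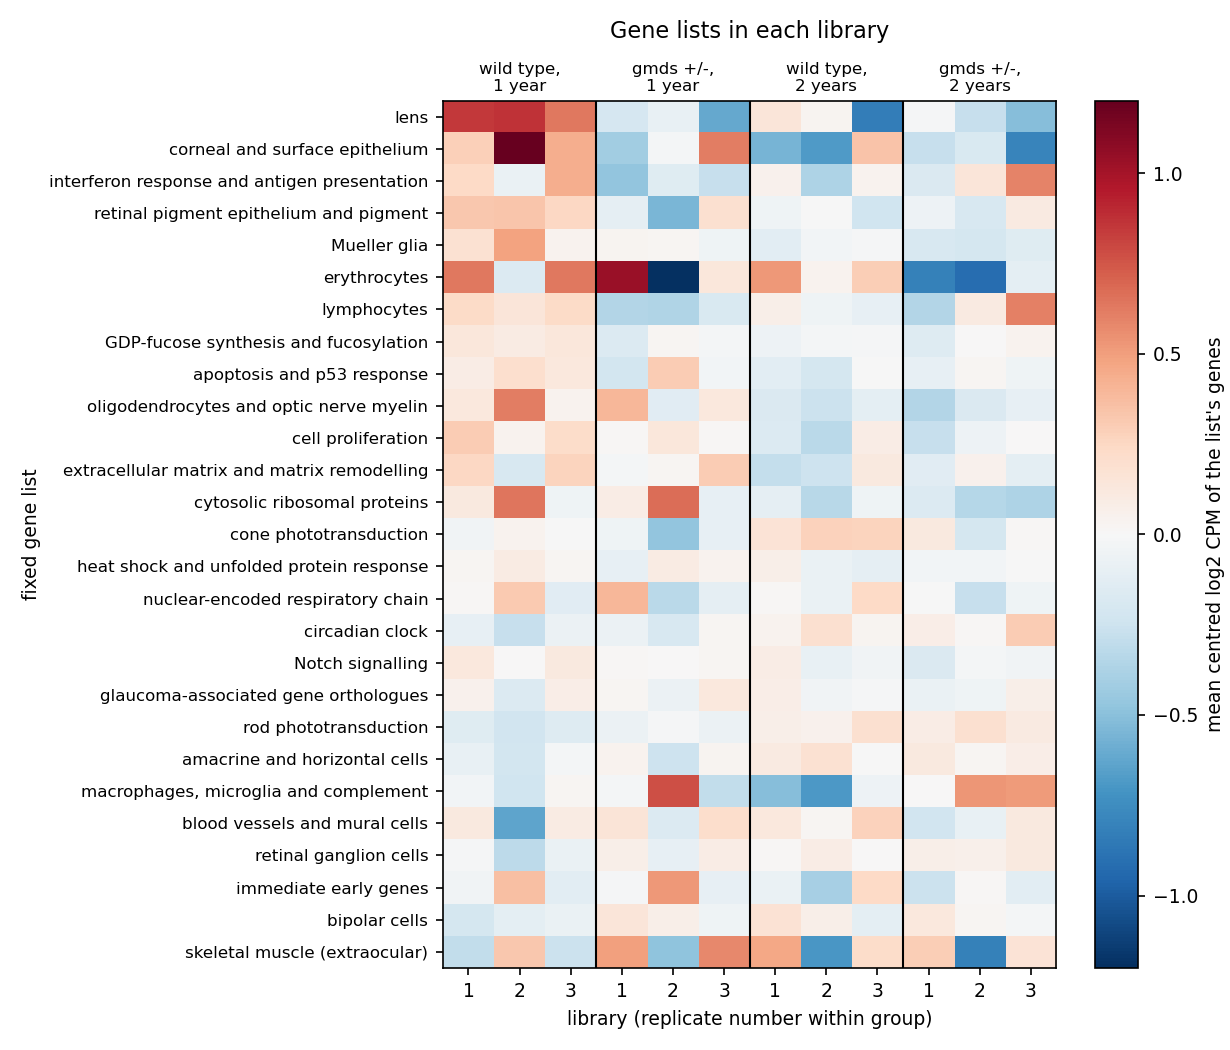
Each cell shows, for 1 library (columns, 3 per group) and 1 of 27 fixed gene lists (each line of cells), the mean log2 CPM of the list's genes centred on the mean of the 12 libraries, on a colour scale from blue (lower) to red (higher). The lens list scores between 0.63 and 0.87 in the wild-type libraries at 1 year and between -0.83 and 0.15 in all others.

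At 2 years, genes of macrophages, microglia and complement were higher in heterozygous eyes as a list, with 31 of 34 above 0. Their median log2 fold change was 0.75 (adjusted p = 1.64e-18, and adjusted p = 0.397 with an estimated correlation). None of them passed over all genes, and 1 rose adjusted over the list alone, grn2 (2.77 ± 0.59), a granulin gene. Erythrocyte genes were lower, with 16 of 17 below 0 and a median of -0.99 (adjusted p = 9.69e-14, and adjusted p = 0.483 with an estimated correlation). No single gene passed edgeR's test over all genes at 2 years (0 of 12202), while 396 had an unadjusted p under 0.05 and DESeq2 called 10 (7 higher, 3 lower). The kinase gene bmp2k had the smallest p. It was at 2.74 ± 1.42 CPM in wild type and 28.9 ± 3.14 CPM in heterozygotes (SD, n = 3 each), a log2 fold change of 3.38 ± 0.49 (adjusted p = 0.234).

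Next to each other on chromosome 25 (20997676 to 21085661), fbxl14a (0.172 CPM in wild type and 8.33 CPM in heterozygotes), gnaia (0.139 and 13.9 CPM) and prr5a were near 0 in all 3 wild-type libraries at 2 years, at adjusted p = 0.72 each. For prr5a the wild-type libraries held 2 counts and the heterozygous ones 205, a ratio of 100 (95% counting interval 27.4 to 834). The cytokine receptor gene csf2rb was higher by 2.23 ± 0.45 (adjusted p = 0.72; on an alternative contig). Lower values were those of the keratin gene krt93 (-2.72 ± 0.61, adjusted p = 0.968), ppp1r14aa (-0.45 ± 0.10, 0.968) and the adrenoceptor gene adrb3a (-1.09 ± 0.29). The gene sco1 was at 4.31 ± 5.26 CPM in wild type and 0.351 ± 0.0281 CPM in heterozygotes. Without wild-type replicate 2 at 1 year 5 genes passed at 2 years, bmp2k, fbxl14a, gnaia and prr5a among them, and 3 without heterozygous replicate 3 at 2 years. Replicate 2 enters through the shared spread, scaling and filter. It was itself low for fbxl14a (0.233 CPM), gnaia (0.299 CPM) and prr5a (0.0333 CPM). The other wild-type libraries at 1 year were not (fbxl14a 7.24 and 9.05 CPM). For bmp2k it was high (19.1 CPM, against 6.89 and 4.91 CPM). So wild-type fish of 1 age differed at these 4 genes, and the calls rest on leaving that fish out.

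In all 8 lists were called at 2 years, and 0 with an estimated correlation or by fry. Interferon and antigen presentation genes (n = 35, median 0.21, adjusted p = 0.00252) and proliferation genes (n = 36, 0.26, 0.0123) were higher, both at adjusted p = 0.919 with an estimated correlation. Genes of the respiratory chain were lower by small amounts in 61 of 63 cases (median -0.16, adjusted p = 3.97e-05). Blood vessel genes (n = 33, median -0.17, adjusted p = 0.00382) and ribosomal protein genes (n = 72, -0.11, 0.0343) were lower too, these 3 lists all at adjusted p = 0.937 with an estimated correlation. Cone genes had a median of -0.11 (n = 30, adjusted p = 0.0104, and adjusted p = 0.919 with an estimated correlation). Adjusted over the list alone gmds, krt93 and the troponin gene tnnt2d (-2.27 ± 0.45) also fell, in the GDP-fucose, corneal and muscle lists, against 0 over all genes. The lens list had a median of -0.04 (adjusted p = 0.529), the ganglion cell list 0.08 (0.445), the glaucoma list -0.03 (0.767) and the Notch list -0.03 (0.26). Leaving out heterozygous replicate 3 at 2 years ended the interferon (median 0.08), proliferation (0.14) and ribosomal calls (-0.03), and wild-type 2 the interferon (0.16), proliferation (0.09) and cone calls (-0.08). Heterozygous 2 ended the proliferation (0.17), cone (-0.04) and ribosomal calls (-0.09), and heterozygous 1 the blood vessel call (-0.07). The ribosomal call also ended without wild-type 1 (-0.01) or 3 (-0.06) at 2 years or heterozygous 1 at 1 year (-0.11). The lens list was called lower at 2 years without wild-type 3 (-0.28) or heterozygous 1 (-0.22). Corneal genes were called lower without wild-type 1 (-0.18) or 2 (-0.23) or heterozygous 1 (-0.25) or 2 (-0.20), and muscle genes without wild-type 2 (-0.41) or heterozygous 1 (-0.30) or 3 (-0.25). Lymphocyte genes were called higher without heterozygous 1 (0.36) and matrix genes without wild-type 3 (0.19). Other calls were kept at a median moved by over 1.5 times. Without wild-type 1 this held for interferon genes (0.32), without wild-type 2 for ribosomal (-0.20) and blood vessel genes (-0.26), and without wild-type 3 for respiratory (-0.09) and blood vessel genes (-0.08). Without heterozygous 1 it held for cone (-0.24), interferon (0.36) and ribosomal genes (-0.17), without heterozygous 2 for respiratory (-0.09) and blood vessel genes (-0.11), and without heterozygous 3 for blood vessel genes (-0.29). The ribosomal call ended with the length trend removed (-0.08, adjusted p = 0.077).

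**Figure D3:**
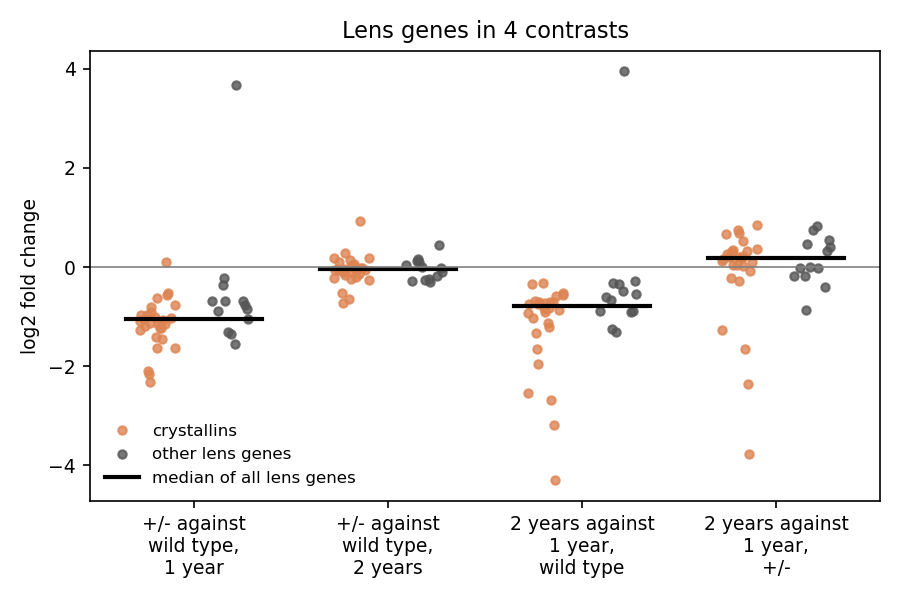
The vertical axis shows the log2 fold change of each of 42 lens genes (orange, 29 crystallins; grey, 13 other lens genes) in 4 contrasts, and the black bar is the median of all 42. The median is -1.05 for heterozygotes against wild type at 1 year and -0.04 at 2 years, -0.78 for 2 years against 1 year in wild type and 0.19 in heterozygotes; the grey point near 4 is lim2.1.

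The test of the difference between the genotype effects at 2 years and at 1 year showed lens genes to differ as a list. The median difference was 1.03, with 41 of 42 above 0 (adjusted p = 7.44e-22, and adjusted p = 0.334 with an estimated correlation). Adjusted over the list alone 4 lens genes passed, cryba2a (1.05 ± 0.28), crygm5 (1.56 ± 0.39), crygs2 (1.08 ± 0.30) and dnase1l1l (1.31 ± 0.37), against 0 over all genes. Interferon and antigen presentation genes differed by 0.88 (adjusted p = 2.34e-10) and pigment epithelium genes by 0.51 (6.13e-05), both at adjusted p = 0.508 with an estimated correlation. Macrophage genes differed by 0.41 (adjusted p = 6.13e-05) and lymphocyte genes by 0.38 (0.00886), both at adjusted p = 0.65 with an estimated correlation. The lymphocyte genes cd8a (3.54 ± 1.02), zap70 (2.66 ± 0.62), il7r (2.02 ± 0.52) and ccl38.6 (2.52 ± 0.77) passed adjusted over the list alone and not over all genes, as did opn1mw2 (-1.38 ± 0.36), opn1mw3 (-1.49 ± 0.38), neflb (-1.03 ± 0.22), nr4a3 (1.47 ± 0.32) and ryr1b. Proliferation genes differed by 0.25 (adjusted p = 0.0328, 0.0823 with the replicate block, and adjusted p = 0.719 with an estimated correlation). With the block in the 1-year libraries alone the proliferation call was kept (camera adjusted p = 0.0453). The effect was lower at 2 years for erythrocyte (-0.62, adjusted p = 0.027), muscle (-0.53, 0.00156), blood vessel (-0.39, 0.00138) and bipolar cell genes (-0.17, 0.0393, and 0.051 with the block), at adjusted p = 0.752, adjusted p = 0.735, adjusted p = 0.719 and adjusted p = 0.65 with an estimated correlation. The bipolar call, too, was kept with the block in the 1-year libraries alone (camera adjusted p = 0.0453). Corneal genes were called with the block (adjusted p = 0.0278) and not without (0.40, adjusted p = 0.0574). With 1 library left out, the muscle call ended without wild-type 1 (-0.43) or 3 (-0.37) or heterozygous 1 (-0.25) or 3 (-0.36) at 1 year, or wild-type 1 (-0.22) or heterozygous 2 (-0.25) at 2 years. The erythrocyte call ended without wild-type 2 (-0.50) or heterozygous 1 (-0.18) or 3 (-0.69) at 1 year, or wild-type 1 (-0.41) or heterozygous 1 (-0.65) or 2 (-0.49) at 2 years. The bipolar call ended without wild-type 1 (-0.14) or heterozygous 1 (-0.19) at 1 year, or wild-type 1 (-0.16) or 2 (-0.17) or heterozygous 2 (-0.19) or 3 (-0.18) at 2 years. The proliferation call ended without wild-type 1 (0.25) or heterozygous 1 (0.23) or 3 (0.27) at 1 year, or wild-type 2 (0.11) or heterozygous 2 (0.16) or 3 (0.21) at 2 years. The blood vessel call ended without wild-type 2 at 1 year (-0.16) and the lymphocyte call without heterozygous 3 at 2 years (0.20). Corneal genes were called without any 1 of 6 libraries: wild-type 1 (0.53) or 3 (0.47) or heterozygous 2 (0.48) or 3 (0.62) at 1 year, or wild-type 3 (0.64) or heterozygous 3 (0.51) at 2 years. The macrophage difference stayed called at 0.73, 0.85 and 0.23 without wild-type 2, heterozygous 2 and heterozygous 3 at 1 year, and at 0.64, 0.75 and 0.27 without wild-type 3, heterozygous 1 and heterozygous 3 at 2 years. Without heterozygous 2 at 1 year, pigment epithelium genes were at 0.26, muscle genes at -0.90 and erythrocyte genes at -1.07. Lymphocyte genes were at 0.21 without heterozygous 3 at 1 year and 0.64 without heterozygous 2 at 2 years, and interferon genes at 0.56 without heterozygous 3 at 2 years. Muscle genes were at -0.86 without wild-type 2 at 2 years, bipolar genes at -0.33 without wild-type 3 and, without heterozygous 1 at 2 years, at -0.29, where blood vessel genes were at -0.25. Without both second 1-year libraries the differences were 0.94 for macrophage, 0.26 for pigment epithelium, 0.40 for proliferation, -1.10 for muscle, -0.99 for erythrocyte and -0.19 for blood vessel genes, all called. Cone, ganglion cell, amacrine, apoptosis, respiratory, matrix, immediate early and ribosomal genes, not called with all libraries, were each called without some library.

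No single gene passed the test of that difference in edgeR (0 of 12202), with 956 at an unadjusted p under 0.05 and 44 called by DESeq2. The smallest p was that of tk2 (3.91 ± 0.50, adjusted p = 0.0694), which was near wild-type level in heterozygotes at 2 years (18.9 ± 8.17 CPM in wild type and 17.0 ± 2.94 CPM in heterozygotes). Next were bmp2k (4.42 ± 0.67, adjusted p = 0.166), the lipid-metabolism gene tlcd2 (1.46 ± 0.26), cmtm3 (2.12 ± 0.40) and the receptor gene tnfrsf18 (3.04 ± 0.61), all 3 at adjusted p = 0.316. In the other direction syne2a was at -0.88 ± 0.17 (-0.05 with the length trend removed) and ryr1b at -1.17 ± 0.24. The genes aktip, smad6a and hdac3 (the latter on an alternative contig) were near 0 in most libraries and high in all 3 heterozygous libraries at 1 year. Their means were 33.0 ± 4.86, 11.6 ± 3.0 and 6.13 ± 0.62 CPM there. Wild-type replicate 3 at 2 years was as high for smad6a (12.3 CPM) and hdac3 (6.14 CPM), so for these 2 the pattern is not particular to those heterozygotes. That library held 3.85 CPM of aktip, well below the 27.7 to 37.2 CPM of the heterozygous libraries at 1 year. The count was 3 without wild-type replicate 2 or heterozygous replicate 3 at 1 year, and 0 or 1 without any other library.

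**Figure D4:**
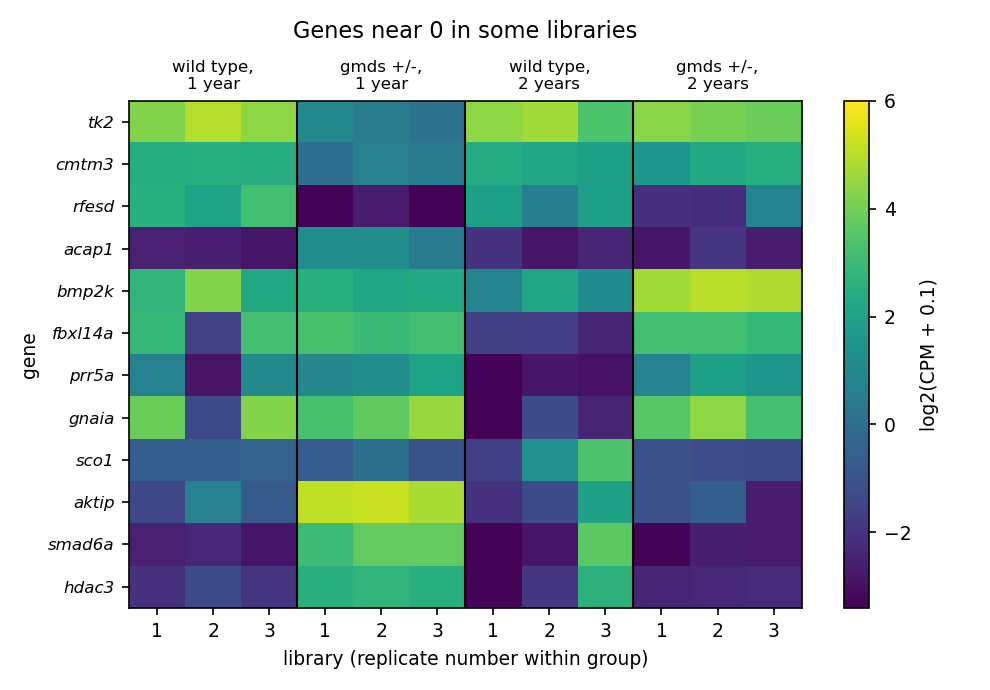
Each cell shows log2(CPM + 0.1) of 1 named gene (vertical axis) in 1 library (horizontal axis, replicate number within each of 4 groups), from dark blue (low) to yellow (high). The genes fbxl14a, prr5a and gnaia are low in the same 4 libraries, the 3 wild-type ones at 2 years and wild-type replicate 2 at 1 year.

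Across all 12202 genes the genotype log2 fold changes at the 2 ages, which share no libraries, correlated weakly (Spearman 0.07, Pearson 0.07, across genes, which are not independent replicates). At an unadjusted p under 0.05 at both ages there were 96 genes, against 56.9 for independent lists. Both p-values of a gene rest on 1 estimate of its spread over all libraries, so the 2 sets are not independent. A count above 56.9 can therefore arise without a repeated effect. Of the 96 genes, 57 (59.4%) had the same direction, against 49.6% with permuted genes (one-sided permutation p = 0.0424), and 39 the opposite one. The permutation treats genes as independent, so this p can be too small. The 57 include gmds, whose fall at both ages follows from the design. With gmds left out, 2 of the 14 genes called at 1 year, syne2a and ephx1, lay on chromosome 20 with gmds (14.3%, against 4.7% of genes tested; Fisher's exact test, two-sided p = 0.137). None lay within 5 Mb of it (0 of 14). At an unadjusted p under 0.01 the share on chromosome 20 was 5.1% of 570 genes at 1 year (Fisher's exact p = 0.611) and 1.4% of 73 genes at 2 years (0.264).

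Genes of rod phototransduction were higher at 2 years than at 1 year in wild-type eyes, with 20 of 23 above 0 (n = 3 fish per age). Their median log2 fold change was 0.30 (adjusted p = 1.44e-05, adjusted p = 0.0212 with an estimated correlation, fry adjusted p = 5.06e-04). Of the rod list 4 genes rose adjusted over the list alone, and 0 over all genes: the transducin gene gnat1 (0.52 ± 0.16), the phosphodiesterase gene pde6gb (0.56 ± 0.15), the channel gene cnga1a (0.66 ± 0.16) and rom1b (0.44 ± 0.13). Of the cone list 5 genes rose adjusted over the list alone, and 0 over all genes. They were the green opsins opn1mw2 (1.47 ± 0.26), opn1mw3 (1.68 ± 0.28) and opn1mw4 (1.09 ± 0.31), the red opsin opn1lw1 (1.62 ± 0.42) and gnb3b (0.48 ± 0.14). The green opsins are tandem copies on chromosome 6, so reads could be split among them. Over all genes 1 gene rose, the phosphatase gene lhpp, from 3.74 ± 0.987 to 14.2 ± 3.61 CPM (1.94 ± 0.24, adjusted p = 0.0494). At an unadjusted p under 0.05 there were 1981 genes, and DESeq2 called 528 (276 higher, 252 lower). The ages were deposited as separate tables, so age and any processing batch cannot be told apart. The lhpp call was lost without any 1 of 7 libraries, the 3 wild-type ones at 1 year among them.

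Lens genes were lower at 2 years in wild type, with 41 of 42 below 0 and a median of -0.78 (adjusted p = 1.59e-18, and adjusted p = 0.223 with an estimated correlation). Of them 22 fell adjusted over the list alone, and 0 over all genes. The comparison of genotypes at 1 year uses the same 3 wild-type libraries at 1 year. Lists and genes that moved alike in both comparisons are therefore not separate findings, since an unusual wild-type group at 1 year would give both. In heterozygotes the lens median with age was 0.19. Corneal genes had a median of -0.74 (n = 30, adjusted p = 4.46e-07, and adjusted p = 0.378 with an estimated correlation), and cldne (-1.22 ± 0.28) and elovl7b (-2.52 ± 0.52) fell adjusted over the list alone. Pigment epithelium genes had a median of -0.47 (n = 25, adjusted p = 1.26e-04), ribosomal protein genes -0.43 (70 of 72 below 0, 8.31e-13), and extracellular matrix genes -0.33 (n = 54, 7.38e-04), all 3 at adjusted p = 0.378 with an estimated correlation. Of the matrix genes 7 fell and 1 rose adjusted over the list alone, against 0 over all genes. Proliferation genes had a median of -0.28 (n = 36, adjusted p = 0.00492) and apoptosis genes -0.23 (n = 31, 0.00566). These 2 lists, and the bipolar (0.19, 0.0117), amacrine and horizontal (0.18, 0.00113), cone (0.13, 0.00716) and ganglion cell (0.10, 0.0117) lists, which were higher, were at adjusted p = 0.378 with an estimated correlation. Myelin genes had a median of -0.48 (adjusted p = 0.00121, and adjusted p = 0.368 with an estimated correlation), Mueller glia genes -0.30 (0.00201, and adjusted p = 0.248 with an estimated correlation) and blood vessel genes 0.29 (0.00492, and adjusted p = 0.492 with an estimated correlation). Macrophage genes had a median of -0.32 (adjusted p = 0.00201) and interferon genes -0.28 (0.00429), both at adjusted p = 0.468 with an estimated correlation. In all 17 lists were called, 6 higher and 11 lower. The genes neflb (0.79 ± 0.16, higher), cd9b (-0.98 ± 0.22) and birc5a (-1.24 ± 0.30) passed adjusted over the list alone and not over all genes, and in the myelin list 3 genes fell and 1 rose. In the same way in lists not called, 4 immediate early genes fell and 2 rose, 4 clock genes rose and 1 fell, ryr1b rose (0.93 ± 0.17), and rfng (-0.65 ± 0.15) and hsp70.3 (-1.12 ± 0.23) fell. Calls ended without wild-type replicate 1 at 1 year for cone (0.07) and bipolar genes (0.20), without 2 for ganglion cell (0.04) and blood vessel genes (0.03), and without 3 for interferon genes (-0.21). They ended without wild-type 1 at 2 years for bipolar genes (0.15), and without wild-type 2 at 2 years for ganglion cell (0.07), interferon (-0.15), macrophage (-0.23) and proliferation genes (-0.21). Muscle genes were called higher without wild-type 2 at 1 year (0.34) or 2 years (0.38), and immediate early genes lower without wild-type 3 at 2 years (-0.33). Without wild-type 2 at 1 year the corneal (-0.39), ribosomal (-0.27), myelin (-0.26), Mueller glia (-0.13) and amacrine lists (0.11) were nearer to 0 and still called. Without wild-type 1 at 1 year ganglion cell genes were at 0.17, blood vessel genes at 0.45 and proliferation genes at -0.14, and without wild-type 3 matrix genes at -0.17, all called. At 2 years cone genes were at 0.08 without wild-type 2, and macrophage genes at -0.56 and blood vessel genes at 0.17 without wild-type 3, all called. Without both second 1-year libraries the ganglion cell (0.05) and blood vessel calls (0.04) ended, corneal genes were at -0.38, ribosomal genes at -0.27, myelin genes at -0.26 and Mueller glia genes at -0.13, and muscle (0.35) and erythrocyte genes (-0.27) were called. Across genes the fold change was higher the longer the transcript (Spearman 0.35), and with that trend removed the ribosomal median was -0.17, and respiratory (0.18) and Notch genes (-0.09) were called. Single genes with small p besides these, all at adjusted p = 0.0941, were lower for the chemokine gene ccl27b (-2.26), the keratan sulphate proteoglycan gene lum (-1.07), aox5 (-1.93) and plek2 (-2.62). Those of pdzd7a (1.08) and the dystrophin gene dmd (0.66, and 0.20 with the length trend removed) were higher.

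In heterozygous eyes tk2 was higher at 2 years than at 1 year (1.44 to 17.0 CPM, 3.58 ± 0.38, adjusted p = 0.0116). The wild-type libraries of both ages held 9.93 to 31 CPM of tk2, so it was low in the 3 heterozygous libraries at 1 year alone. The collagen chaperone gene serpinh1b fell (66.8 ± 10.5 to 21.2 ± 6.05 CPM, -1.65 ± 0.22). The gene of an inhibitor of myosin phosphatase, ppp1r14aa, fell (55.2 ± 4.15 to 32.3 ± 0.855 CPM, -0.77 ± 0.10), as did acap1 (1.93 ± 0.544 to 0.0845 ± 0.063 CPM), all 3 at adjusted p = 0.0245. The zinc transporter gene slc39a1 lay outside the rule for named genes and was chosen after its values were seen. It was at 1.88 ± 0.417 CPM at 1 year and had no count in any library at 2 years, where 3 counts correspond to 0.0941 to 0.163 CPM. In wild type slc39a1 was near 0 at both ages (0.046 CPM at 1 year and 0.0247 CPM at 2 years), and acap1 was at 0.0584 CPM at 1 year. So slc39a1 was on in the 3 heterozygous libraries at 1 year alone, and its fall is no general loss with age. These were the 5 genes called (1 higher, 4 lower), with 1025 at an unadjusted p under 0.05 and 58 called by DESeq2. The count was 0 without heterozygous replicate 1 at 1 year and 12 without wild-type replicate 3 at 2 years, and the batch limit for age applies here too.

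Ribosomal protein genes were lower at 2 years in heterozygotes, with 70 of 72 below 0 and a median of -0.52 (adjusted p = 4.14e-24, and adjusted p = 0.498 with an estimated correlation). The genes rpl7a (-0.73 ± 0.16), rpl35 (-0.79 ± 0.20) and rpl37 (-1.0 ± 0.24) fell adjusted over the list alone, against 0 over all genes. Interferon and antigen presentation genes were higher (n = 35, median 0.42, adjusted p = 1.06e-06, and adjusted p = 0.498 with an estimated correlation). Rod genes had a median of 0.17 (n = 23, adjusted p = 0.00468, adjusted p = 0.182 with an estimated correlation, fry adjusted p = 0.0313). Lymphocyte (median 0.25, adjusted p = 0.04) and amacrine cell genes (0.11, 0.041) were higher. Erythrocyte (-0.96, adjusted p = 3.88e-04), corneal (-0.45, 0.00114), immediate early (-0.33, 0.04) and matrix genes (-0.15, 0.0153) were lower, and these 6 lists were all at adjusted p = 0.674 with an estimated correlation. In the lymphocyte list cd8a (2.91 ± 0.77), zap70 (1.95 ± 0.45), il7r (1.48 ± 0.37) and ccl38.6 (1.87 ± 0.56) rose adjusted over the list alone, as did grn2 (2.91 ± 0.60) and lrit3a (0.79 ± 0.18), and ccnd1 fell (-0.80 ± 0.16), in lists not called. Muscle genes had a median of -0.48 (adjusted p = 0.00415, and adjusted p = 0.734 with an estimated correlation) and respiratory chain genes -0.12 (0.0386, and adjusted p = 0.818 with an estimated correlation). Myelin genes had a median of -0.28 (adjusted p = 0.00614) and Mueller glia genes -0.12 (0.0386), both at adjusted p = 0.498 with an estimated correlation. Clock genes had a median of 0.09 (adjusted p = 0.0108, and adjusted p = 0.569 with an estimated correlation). The lens list was called higher (median 0.19, adjusted p = 0.0405, and adjusted p = 0.797 with an estimated correlation) although the mean of its members was -0.02, and without heterozygous replicate 1 at 2 years its median was -0.02. In all 15 lists were called, 6 higher and 9 lower. Without heterozygous replicate 1 at 1 year the calls of erythrocytes (-0.27), Mueller glia (-0.17), lymphocytes (0.11), muscle (-0.24) and myelin (-0.20) ended and respiratory genes turned to 0.12. Without heterozygous 2 those of amacrine cells (0.01), Mueller glia (-0.17), immediate early genes (-0.06) and the clock (0.06) ended. Without heterozygous 3 those of rods (0.17), cornea (-0.31), matrix (-0.10), Mueller glia (-0.20), lymphocytes (0.49), muscle (-0.21), myelin (-0.26), amacrine cells (0.13) and lens (0.07) ended. At 2 years, heterozygous 1 left out ended those of matrix (-0.13), immediate early (-0.32) and amacrine cells (0.10). Heterozygous 2 left out ended Mueller glia (-0.21), lymphocytes (0.30), respiratory (-0.07), muscle (-0.26) and amacrine cells (0.12). Heterozygous 3 left out ended lymphocytes (0.12), respiratory (-0.11), immediate early (-0.28) and clock (0.09). The amacrine call also ended without wild-type 1 (0.12) or 2 (0.11) at 1 year or wild-type 3 at 2 years (0.12), and the lens call without wild-type 1 (0.19), 2 (0.19) or 3 (0.20) at 1 year or 1 at 2 years (0.19). Macrophage genes were called higher without any 1 of the 6 wild-type libraries (0.17 to 0.19), heterozygous 2 at 1 year (0.39) or heterozygous 1 at 2 years (0.34). Cone genes were called higher without heterozygous 1 at 1 year (0.22) or heterozygous 2 or 3 at 2 years (0.21 each), and blood vessel genes lower without heterozygous 2 at 1 year (-0.25) or 3 at 2 years (-0.23). Still called, ribosomal genes were at -0.27, respiratory genes at -0.26 and muscle genes at -0.80 without heterozygous 2 at 1 year, as without both second libraries. So were matrix (-0.23) and clock genes (0.15) without heterozygous 1 and clock genes (0.19) without heterozygous 3 at 1 year. At 2 years so were lymphocyte (0.42), Mueller glia (-0.20) and clock genes (0.15) without heterozygous 1, rod (0.11), lens (0.30) and matrix genes (-0.23) without heterozygous 2, and interferon (0.22), Mueller glia (-0.21) and lens genes (0.29) without heterozygous 3. Without both second 1-year libraries the Mueller glia (-0.17), amacrine (0.01), lymphocyte (0.19), immediate early (-0.06) and clock calls (0.06) ended, and macrophage (0.39) and blood vessel genes (-0.25) were called. With the length trend removed the Mueller glia (-0.10) and respiratory calls (-0.05) ended, clock genes stayed called at 0.05, and cone and macrophage genes were called (0.11 each).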

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

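The tests weighed here for lens and macrophage genes were chosen only after the result was seen, while the test of the difference between ages and the counts of splits were chosen before. For 10 of the 27 gene lists, the genotype effect at 2 years differed from that at 1 year by camera's test of the difference itself. Median differences were 1.03 for lens, 0.88 for interferon and antigen presentation, 0.51 for pigment epithelium, 0.41 for macrophage, 0.38 for lymphocyte and 0.25 for proliferation genes. They were -0.62 for erythrocyte, -0.53 for muscle, -0.39 for blood vessel and -0.17 for bipolar cell genes. With an estimated correlation 0 of the 27 lists passed (lowest adjusted p = 0.334), and fry called 0.

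Lens genes were lower in heterozygotes than in wild type at 1 year (median -1.05, 40 of 42 genes below 0), a call that was lost with an estimated correlation (adjusted p = 0.146, and 0.143 with the length trend removed). The wild-type group at 1 year scored above the other groups. Library scaling was argued against as the whole cause, because the median was -0.96 under the scaling that brought it nearest to 0. The same holds for transcript length, because the median was -0.91 with each library's length trend removed, and 28 genes fell adjusted over the list alone with and without that step. A different amount of lens in the samples may account for the pattern: 28 of 29 crystallins (median -1.11) and 12 of 13 other lens genes (median -0.76) lay below 0, and their medians differed by -0.35 (two-sided permutation p = 0.0141), within the bound of 0.5 set for it. A change of expression within the lens, with genotype or with age, was not tested and stays open.

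Macrophage, microglia and complement genes were higher in heterozygotes at 2 years (median 0.75, 31 of 34 above 0), a call that was lost with an estimated correlation (adjusted p = 0.397) and with fry (adjusted p = 0.957). More blood in the heterozygous samples was argued against, because erythrocyte genes had a median of -0.99 there, with 16 of 17 below 0 and list scores that did not overlap between the genotypes. A single library was argued against as the whole cause, because the lowest median with 1 of the 6 libraries left out was 0.55 (without heterozygous replicate 3) and the highest 0.97. More macrophages or a higher expression in them in heterozygous eyes at 2 years is a hypothesis that could account for these values, and it was not tested; counts of these cells in sections of such eyes would test it.

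Other splits of the same libraries were run through the same tests. For the difference between ages 100 of 200 possible splits were drawn, and 38 gave at least the real 10 lists, with 16 as the highest other, so chance cannot be excluded for the lists. These splits mix those that part the pairs of same-numbered 1-year libraries with those that do not. Of the 41 that part all 3 pairs, the real one among them, 15 gave at least 10 lists (highest other 16, and 16 among the rest). The count of genes decides nothing, since all 100 must give at least the real 0 (edgeR, with 956 at an unadjusted p under 0.05 and 44 by DESeq2). The highest other gave 65 genes, which points to a structure of the samples that was not tested, and the splits that leave a pair together gave at most 2. The comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. At 1 year, 1 of 10 splits gave as many genes as the real 14 (highest other 3) and 6 of 10 as many lists as the real 9 (highest other 13). Of the 4 splits that part all 3 pairs of same-numbered libraries, the real one among them, the highest other gave 1 gene and 10 lists, and the splits that keep 2 pairs together gave up to 3 genes and 13 lists. At 2 years 10 of 10 gave at least the real 0 genes in edgeR, as any split must (highest other 3, with 396 at an unadjusted p under 0.05 and 10 by DESeq2) and 6 of 10 the real 8 lists (highest other 12). For age in wild type 2 of 10 gave the real 1 gene (highest other 1) and 1 of 10 the real 17 lists (highest other 13). For age in heterozygotes 2 of 10 gave the real 5 genes (highest other 9) and 1 of 10 the real 15 lists (highest other 12).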

How the results depend on the processing

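The robust fit, voom weights, all transcripts, removal of the length trend, the block in the 1-year libraries alone and leaving out both second 1-year libraries were chosen only after the data were seen. The fold change of gmds kept its sign under all alternatives run, at -1.2 to -0.71 at 1 year and -1.14 to -0.79 at 2 years with 1 library left out. Counts of genes depended on the tool and the libraries. With edgeR 14, 0, 0, 1 and 5 genes passed for genotype at 1 year, genotype at 2 years, the difference between ages, age in wild type and age in heterozygotes, with 1752, 396, 956, 1981 and 1025 at an unadjusted p under 0.05, and DESeq2 called 350, 10, 44, 528 and 58. Fitting the 2 groups of a comparison alone gave 50 (genotype at 1 year), 1 (2 years), 8 (age in wild type) and 9 (heterozygotes). An adjusted p of 0.1 gave 44 at 1 year, 1 for the difference and 21 for age in wild type, and no filter gave 1 for the difference. Quality weights gave 6 at 1 year, 1 at 2 years and 116 for age in wild type, and all transcripts 2 for the difference and 2 for age in wild type. Removing the length trend gave 9 at 1 year and 0 for age in wild type. Size factors, total counts, the CPM filter, the fold threshold and the robust fit left each count within 1.5 times.

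The replicate block gave 1 gene for genotype at 1 year (1 also with the block in the 1-year libraries alone), and a share of 0% on the gmds chromosome. The numbers were not taken to pair other groups, because their correlations were not all above 0.1. Same-numbered libraries correlated at -0.02, -0.06 and -0.2 for genotype at 2 years and at -0.02, -0.11 and -0.14 for age in wild type. For age in heterozygotes they correlated at 0.06, 0.2 and 0.08. Every heterozygous library at 2 years correlated best with its own number at 1 year, so a pairing there stays open. In these 3 comparisons the block gave 0 genes at 2 years (10 by DESeq2), 0 for age in wild type and 1 for age in heterozygotes, and 7, 17 and 17 lists against 8, 17 and 15. The proliferation call at 2 years was lost (adjusted p = 0.0729), and for age in heterozygotes the cone and macrophage lists were called in addition. For the difference between ages it gave 0 genes and 9 lists. Beyond these and the calls given beside their results, the block changed no other list call.

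Of the lists, 9, 8, 10, 17 and 15 were called in the 5 comparisons, 0, 0, 0, 1 and 0 with an estimated correlation, and 3, 0, 0, 1 and 1 with fry. Both second 1-year libraries left out gave 5 genes at 1 year, 5 at 2 years, 3 for the difference and 4 for age in wild type, and a correlation of -0.004 between the ages (0.066 with all).

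With 1 library left out, genes at 1 year numbered 1 to 86: 1 without each wild-type library at 1 year, 5 and 86 without heterozygous 1 and 3, and 4, 38, 3 and 2 without wild-type 2 and 3 and heterozygous 1 and 2 at 2 years. The share on the gmds chromosome (14.3%) was 0 to 20, being 0 without these wild-type 1-year libraries, wild-type 2 and heterozygous 1 and 2 at 2 years, and 4.7 without heterozygous 3 at 1 year. Genes at 2 years were 0 to 5: 5 without wild-type 2 at 1 year, 1 and 3 without heterozygous 2 and 3 at 2 years. The difference gave 0 to 3: 3 without wild-type 2 or heterozygous 3 at 1 year, and 1 without heterozygous 2 at 1 year, wild-type 3, heterozygous 1 or 2 at 2 years. Age in wild type gave 0 to 6: 0 without wild-type 1 or 3 or heterozygous 3 at 1 year or heterozygous 1 or 3 at 2 years, 3 to 6 without the other libraries except heterozygous 2 at 2 years (1). Age in heterozygotes gave 0 to 12: at 1 year 1, 9 and 1 without wild-type 1, 2 and 3, 0 and 8 without heterozygous 1 and 3; at 2 years 2 and 12 without wild-type 2 and 3, 3 and 1 without heterozygous 1 and 3. The correlation between ages was -0.007 (without heterozygous 3 at 1 year) to 0.178 (without heterozygous 1). Lists at 1 year were 5 to 13 (5 without heterozygous 3), for the difference 6 to 17 (6 without heterozygous 1 at 1 year or 2 at 2 years, 17 without heterozygous 2 at 1 year), and for age in heterozygotes 6 to 16 (6 without heterozygous 3 at 1 year).

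Some lists changed direction. Ribosomal genes went from -0.05 to 0.15 at 1 year without wild-type 2 (range -0.24 to 0.15) and from -0.06 to 0.13 for the difference without heterozygous 2 at 1 year (-0.25 to 0.13). Respiratory genes went from -0.12 to 0.12 for age in heterozygotes without heterozygous 1 at 1 year (-0.26 to 0.12), and lens genes from 0.19 to -0.02 without heterozygous 1 at 2 years (-0.02 to 0.30). With the length trend removed, syne2a at 1 year was -0.03 and respiratory genes for age in wild type 0.18 (from -0.04). Without both second 1-year libraries, macrophage genes at 1 year were -0.33 (from 0.15) and respiratory genes 0.21 (from -0.03), both called. The cause was not tested. Of the values of named genes, under alternatives other than a left-out library, 3804 kept direction and side of the threshold. A further 96 changed direction without a call in either fit, 1 changed it with a call, 68 lost and 66 gained a call. Of single lists 1040 kept both, 31 changed direction without a call, 3 changed it with a call, 134 lost and 34 gained a call. With 1 library left out, 3365 values of named genes kept both, 188 changed direction without a call, 109 lost and 10 gained a call. Of single lists 1353 kept both, 101 changed direction without a call, 4 changed it with a call, 102 lost and 60 gained a call. Depth sets a floor of 0.0868 to 0.229 CPM per library, under which no difference was detectable. In simulated data for 1 year, with no low-count gene among those changed, 10% of 1.5-fold changes were called.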

Other observations

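All tests in this part were chosen only after the result was seen, and the genes named were chosen after their values were seen. Some genes differed between the genotypes in the same direction at both ages, which share no libraries but share the estimate of each gene's spread. The gene slc35c2, for a Golgi transporter linked to GDP-fucose (chromosome 23, 20431548 to 20443566), was higher in heterozygotes at 1 year (4.69 ± 0.479 and 7.83 ± 1.36 CPM, SD, n = 3 each; log2 fold change 0.73 ± 0.24) and at 2 years (4.72 ± 1.11 and 7.25 ± 1.53 CPM, 0.62 ± 0.23). With edgeR's quasi-likelihood test it did not pass at either age (adjusted p = 0.21 and adjusted p = 1). The ganglion cell marker rbpms2a was at 0.69 ± 0.17 and 0.39 ± 0.17, the phosphatase gene lhpp at 1.40 ± 0.24 and 0.84 ± 0.23, and mlf1 at 1.40 ± 0.22 and 0.87 ± 0.22 (log2, at 1 and 2 years). The selenoprotein gene selenoj was at -0.50 ± 0.12 and -0.44 ± 0.12 and the glycolytic gene tpi1b at -1.01 ± 0.33 and -0.88 ± 0.33. Of these, mlf1 alone passed at 1 year (adjusted p = 0.0451) and none at 2 years (adjusted p = 1 for each).

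Genes with a small p were not spread evenly over the chromosomes. At 1 year chromosome 7, which does not carry gmds, held 43 of 571 genes with an unadjusted p under 0.01 (7.5%, against 4.6% of the genes tested; Fisher's exact p = 0.00139, adjusted p = 0.0347 over 25 chromosomes). Of the 14 genes called, 4 lay there, namely the neighbours tk2 and cmtm3, and acap1 (20058857 to 20103332) and zgc:103586. At 2 years chromosome 25 held 9 of 74 such genes (12.2%, against 2.8%; Fisher's exact p = 2.23e-04, adjusted p = 0.00557), among them fbxl14a, gnaia and prr5a. Neighbouring genes are not independent, so these p-values are too small.

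Some genes were near 0 in some libraries and high in others, with a gap of at least 3 (log2) between at least 2 libraries on each side and at least 2 CPM in the highest library. Of 12202 genes 106 were of this kind, and 74 of them have 1 copy on the main assembly. These 74 formed 14 pairs within 100 kb, on 9 chromosomes, against 0.8 on average and 3 at most in 200 random sets of genes. Examples were asah1a, mtus1a and pdgfrl on chromosome 14, low in 2 heterozygous libraries at 1 year and 1 wild-type library at 2 years. Another pair was brf1b and btbd6b on chromosome 20. There btbd6b (20927827 to 20932782) lies within brf1b (20901791 to 21016899), so these 2 may count the same reads. The genes of the other pairs do not overlap. Of the 14 genes called at 1 year 0 met this rule. It leaves out tk2, whose gap was smaller (1.91 CPM in the highest of its low libraries and 9.93 CPM in the lowest of the others).

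A haplotype or structural variant carried by individual fish may account for such neighbours, since the median Pearson correlation of the pairs over the 12 libraries was 0.98 (0.94 to 1), against -0.02 for pairs on other chromosomes. The highest median with genes permuted was 0.47 (one-sided permutation p = 0.001, the smallest that 1000 permutations can give). Reads shared with a near-identical copy or an alternative contig were argued against as the cause of most, because 30.2% of the 106 genes (32) had such a copy, although this is above the 6.8% of all genes tested (Fisher's exact p = 2.73e-13). No genome sequence of these fish was used here, so the variants themselves were not seen. Among siblings, genotype groups of 3 fish could differ at such regions without any effect of gmds, and this stays open for tk2, cmtm3 and acap1, and for slc39a1 and gngt2a, which met the rule above. The libraries low for gngt2a were 3 heterozygous ones at 1 year and 2 at 2 years, with 0 wild-type ones at either age. At 2 years edgeR's unadjusted p for gngt2a was 0.127.

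Transcript length was related to the fold changes across genes, which are not independent replicates. Spearman's rho was 0.28 for genotype at 1 year and 0.07 at 2 years, and 0.35 for age in wild type and 0.15 in heterozygotes (10609 genes). Within single libraries rho was lowest in wild-type replicate 2 at 1 year (-0.41). That library and heterozygous replicate 2 at 1 year also had the lowest quality weights of the 12 (0.41 and 0.5).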
